A study of Mus musculus with 8 samples.

How the data were processed

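Total RNA was extracted from mouse lung tissue with Trizol, purified on columns, labelled with biotin and hybridized to single-colour oligonucleotide arrays. The 8 arrays comprise 3 from wild type lung and 5 from tumour samples of mice with oncogenic Kras in CC10-expressing cells, aged 8 to 10 weeks. Per the submitters' processing notes, the deposited values are log2 RMA signals made with the affy package, whose version is not given in the sources used here. No reads are involved, and no aligner or genome build applies.

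The deposited table holds 34760 probe sets with 2 decimals, with values from 1.02 to 13.14 and upper quartiles of the arrays between 7.72 and 7.75, and it was used without further normalization. The probe table at hand covered 22961 probe sets, of which 21640 name 1 gene and 1321 several. The other 11799 have no name here and entered only 1 alternative. Entrez identifiers matched a RefSeq gene table for 21553 probe sets, and 0 symbols changed. For the 954 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which left 19937 genes. Some of the series' items are not reported here. Kras and Acsl3 are not analysed here, and no statement is made on the level of Kras or on which allele is expressed. The number of unused sample columns is 0.

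Groups were compared with limma 3.58.1 in R 4.3.3, with a linear model of 2 group means, empirical Bayes variances (6 residual and 4.54 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Values are tumour minus control on the log2 scale with the moderated standard error (SE), and means are given with the SD of the arrays. The precision is limited by the number of arrays.

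Gene lists were written from general knowledge of lung and tumour biology before the values were examined. They number 36 with 728 members, of which 671 were measured, 19 have only probe sets shared by several genes and 38 are not analysed here. The 34 lists with at least 5 measured members were tested with camera at the preset correlation of 0.01, adjusted over the 34 lists, and again with the correlation estimated from the data. Counts of members called use the adjusted p over all genes, and a second count adjusts over the list alone. Members shared with other lists number 4 for lipogenesis, 3 for elongation and desaturation, 2 each for fatty acid uptake, phospholipids, NADPH supply, xenobiotic metabolism and club cells, 6 for type 2 cells, and 1 each for NRF2 targets, ERK output, chemokines, MHC class II and adipocytes.

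Genes were named by a rule fixed beforehand. It names the 10 largest rises and 10 largest falls among called genes whose tumour values all lie on one side of the control values, without predicted or unnamed genes, immunoglobulin and T cell receptor segments, small RNAs and sex-linked genes. It also names up to 3 called members with the largest change in each list, plus the called member with the largest change in the opposite direction. Finally it names 12 measured genes whether changed or not (Scgb1a1, Sftpc, Fasn, Acaca, Acly, Scd1, Scd2, Srebf1, Elovl6, Acss2, Mki67 and Dusp6). Where 5 or fewer members of a list rose or fell, further members were named. In some lists, but not all, members that missed the threshold were named as well. These further genes were chosen after their values were seen.

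The alternatives were a variance trend with robust moderation, removal of genes with a mean under 5.42 (13292 genes left), a second quantile normalization, centring of each array on its median, the mean of a gene's probe sets, array weights, the replicate number as a block, an adjusted p under 0.01, every probe set, leaving out each array in turn, camera on ranks, camera with an estimated correlation, and fry, which tests a list against no change rather than against the other genes. Averaging tumour replicates 3 and 4 was added after the data were seen. All 56 splits of the 8 arrays into 3 and 5 were also fitted.

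The fit was tested on simulated data with the group sizes and gene number of this comparison in 10 runs. Of 1000 genes given a log2 change of 0.5, 60.5% were called, of 1000 with a change of 1, 94.8%, and 4.19% of the calls were false. In 20 simulated runs a list of 20 members with a shift of 0.3 was called 20 times, and 2 of 660 lists without a shift were called. The simulated genes were drawn independently, whereas the correlation estimated from the data reached 0.798 for the cell cycle list. The simulation therefore does not measure the error of the list calls in these data. Far fewer genes were changed in each simulated run than the 40.6% called in the data. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.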

Results

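Gene expression was measured in whole-tissue RNA from mouse lung on 8 single-colour oligonucleotide arrays. All mice were 8 to 10 weeks old. The 3 control arrays came from lungs of wild type mice without tumours. The other 5 came from mice with a conditional oncogenic Kras allele, switched on by Cre recombinase under the CC10 promoter, which is active in the club (Clara) cells of the airway. The sample titles call these samples lung tumours, whereas the collection protocol calls them tumour-bearing lungs, so the share of tumour tissue in each is unknown. They are called tumour samples here. Each array carries 34760 probe sets, and 19937 genes with a probe set of their own were tested. The medians of the arrays lay between 5.9 and 5.99 on the log2 scale. The labels number the samples within each group but do not state that each came from a separate animal, so the p-values measure only the spread between these samples, which may be technical.

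The groups stood far apart. The first principal component held 75.8% of the variance and separated every tumour array from every control array. Pairs of control arrays correlated at 0.996 to 0.997 over all genes, pairs of tumour arrays at 0.99 to 0.997, and pairs of 1 control and 1 tumour array at 0.961 to 0.971. Among the tumour arrays, replicate 2 lay apart on the second component (9.02% of the variance) and replicate 5 on the third (5.18%). Xist, the transcript of the inactive X chromosome, was between 10.72 and 11.18 on all 8 arrays, and 3 Y-linked genes were low on all of them, so none of the 4 measured sex-linked genes passed the test and 0 did when adjusted over the list alone.

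The comparison asked which genes and pathways differ between lung tumours driven by oncogenic Kras and wild type lung, and the series title singles out de novo lipogenesis. In the de novo lipogenesis list 11 of 18 genes rose in the tumour samples, among them malic enzyme and fatty acid synthase. The fatty acid elongase Elovl6, the acetate-activating enzyme Acss2 and Thrsp fell. Camera did not call the list against the other genes (adjusted p = 0.14), whereas fry, which tests against no change, called it (adjusted p = 0.000255). Of the genes listed for alveolar type 2 cells 16 of 19 rose, for macrophages 14 of 22, for ERK output 16 of 22, for NADPH supply 10 of 13 and for oxidative phosphorylation 20 of 29. Markers that fell were 25 of 26 for endothelium, 17 of 20 for fibroblasts, 12 of 16 for smooth muscle, 13 of 14 for heart muscle, 21 of 22 for ciliated, 11 of 18 for club, 19 of 20 for T and natural killer, and 12 of 14 for B and plasma cells. Each of these lists other than lipogenesis was called as a set at a preset correlation between genes, and camera with an estimated correlation called 0. With limma, 4584 genes were higher and 3513 lower in the tumour samples at an adjusted p under 0.05, which is 40.6% of the genes tested. Of these, 409 rose and 968 fell at least 2-fold.

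The median change of all genes was 0.075 on the log2 scale, and 56.6% of the called genes were higher. Centring each array on its median moved that share to 70.4%, with 7026 genes higher and 2950 lower and a median change of 0.15, so the balance of rises and falls depends on how the arrays are centred. In 41.5% of the genes the 5 tumour values all lay on one side of the 3 control values, against 3.57% by chance.

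The largest rise was that of Slc26a4, the anion exchanger pendrin, from 5.50 ± 0.13 (SD, n = 3) to 9.40 ± 0.67 (SD, n = 5), a 14.9-fold difference (log2 change 3.90, SE 0.31, limma adjusted p = 3.3e-06). Tnfsf9, a costimulatory ligand of the TNF family, followed with a log2 change of 3.55 (SE 0.33, adjusted p = 9.72e-06), and the receptor tyrosine kinase Ros1 with 3.21 (SE 0.12, adjusted p = 5.84e-08). Gpnmb, a glycoprotein of macrophage lysosomes, rose by 2.96 (SE 0.08) to 10.47 ± 0.10 (SD, n = 5). Fetub, a secreted protease inhibitor, rose by 2.93, the lysosomal protease Ctsk by 2.88, the proton pump subunit Atp6v0a4 by 2.85, the cornified envelope precursor Sprr1a by 2.81 and the arginine methyltransferase Prmt8 by 2.79. Ear6, a ribonuclease of eosinophils and macrophages, rose by 3.02, but its probe set cannot be assumed to separate it from close paralogs. Adjusted p-values of these 10 genes lay at 9.72e-06 or below.

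Car3, a carbonic anhydrase abundant in muscle and fat, fell the most, from 9.77 ± 0.47 (SD, n = 3) to 5.27 ± 1.12 (SD, n = 5), which is 22.7-fold lower (log2 change -4.50, SE 0.53, limma adjusted p = 5.79e-05). The retinol-esterifying enzyme Lrat fell by 4.08 (SE 0.32, adjusted p = 2.72e-06), and Ms4a1, a surface antigen of B cells, fell by 3.51 (SE 0.13, adjusted p = 5.76e-08). The matrix proteoglycan Ogn fell by 3.36, the natriuretic peptide clearance receptor Npr3 fell by 3.30, the cardiac actin Actc1 fell by 3.26 and the sulfotransferase Sult1d1 fell by 3.25. Bank1, an adaptor of B cell receptor signalling, fell by 3.23, the secreted growth factor Bmp6 fell by 3.20, and Nkg7, a granule protein of cytotoxic lymphocytes, fell by 3.18. A group mean under 5.42, the level below which genes were counted as low in signal, makes the size of a change inexact and can understate it. At least 1 group mean lies under it for Car3, Ms4a1, Sult1d1, Bank1 and Ear6 here and for Ncr1 (3.88 in the tumour samples), Gzma, Spib, Pln, Mmp3, Adipoq, Ngp, Elovl4, Pcyt1b, Slc27a2, Slc27a3, Slc27a6, Gkn2, Gkn3, Cldn2, Ereg, Csf2 and Epb42 below.

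**Figure D1:**
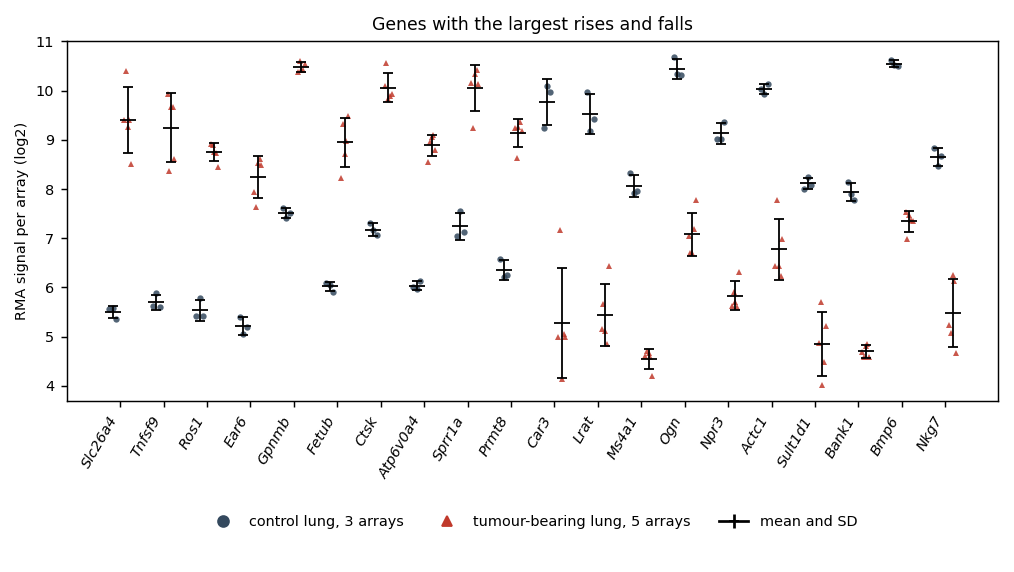
RMA signal on the log2 scale (vertical axis) for the 10 genes with the largest rise and the 10 with the largest fall, with 3 control arrays and 5 tumour arrays as points and the mean and SD as bars. Slc26a4 moves from a mean of 5.50 to 9.40 and Car3 from 9.77 to 5.27, and no tumour point overlaps the control points of the same gene.

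In the de novo lipogenesis list, which was fixed before the data were examined, 11 of 18 measured genes rose, 3 fell and 4 did not pass the test. Me1, which supplies NADPH, rose by 1.13 (SE 0.09, limma adjusted p = 4.56e-06). Fasn, which builds palmitate, rose from 11.12 ± 0.02 (SD, n = 3) to 11.97 ± 0.13 (SD, n = 5), or 0.85 on the log2 scale (SE 0.08, adjusted p = 1.57e-05). Srebf1, the transcription factor that drives lipogenic genes, rose by 0.73 (SE 0.07, adjusted p = 1.48e-05), and Acaca, the carboxylase that makes malonyl-CoA, by 0.66 (SE 0.07, adjusted p = 4.16e-05). Rises were also measured for Acly, which makes cytosolic acetyl-CoA from citrate (0.39, SE 0.11, adjusted p = 0.0154), and for the stearoyl-CoA desaturases Scd1 (0.25, adjusted p = 0.0143) and Scd2 (0.22, adjusted p = 0.0314). The signal of Scd1 (12.26 in the controls) lies near the top of the measured range, where differences can be understated. Elovl6 fell by 0.89 (SE 0.09, adjusted p = 2.8e-05), Acss2 fell by 0.85 (SE 0.10, adjusted p = 4.91e-05), and Thrsp, a regulator of lipogenesis, fell by 0.34. The other 4 genes missed the threshold with all 8 arrays, with changes of -0.30 for Acacb, -0.25 for Nr1h3, -0.034 for Pnpla3 and 0.045 for Mlxipl.

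Adjusted over the list alone, 14 lipogenesis genes passed. As a set the list was not called against the rest of the genes (median change 0.24, camera adjusted p = 0.14). The mean of the list stood at 0.13 to 0.27 in the tumour arrays and at -0.018 to 0.021 in the controls. Leaving out 1 control array at a time lowered the number of lipogenesis genes that rose to 6 without control replicate 2 and 7 without control replicate 3, and 5 genes fell without tumour replicate 2. Among the named genes, Acly missed the threshold without control replicate 1 or 2 (adjusted p up to 0.0526), Scd1 without control replicate 2 or 3 (up to 0.0711), Scd2 without control replicate 2 or 3 or tumour replicate 5 (up to 0.149) and Thrsp without control replicate 1 or 2 or tumour replicate 1 (up to 0.125). Scd2 also missed it after a second quantile normalization, with a change of 0.12, and Scd1 and Scd2 with the replicate number as a block (0.23 and 0.21). In the same tumour samples 16 of 19 alveolar type 2 markers and 14 of 22 macrophage markers rose.

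**Figure D2:**
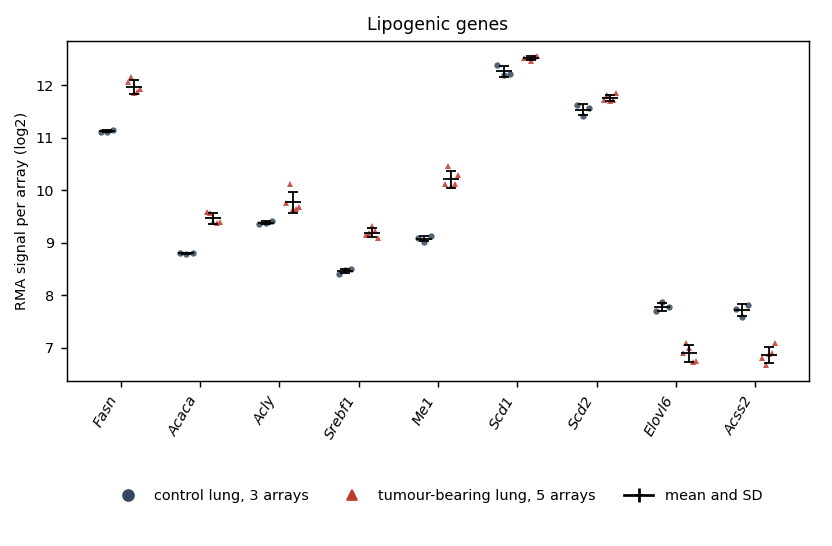
RMA signal on the log2 scale (vertical axis) of 9 lipogenic genes, with 3 control arrays and 5 tumour arrays as points and the mean and SD as bars. Fasn moves from a mean of 11.12 to 11.97 and Me1 from 9.08 to 10.21, whereas Elovl6 moves from 7.78 to 6.89.

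Other lipid pathways changed in part. For fatty acid elongation and desaturation, which shares Elovl6, Scd1 and Scd2 with the lipogenesis list, 9 of 19 genes rose, 5 fell and 5 did not pass. The elongases of long-chain fatty acids Elovl7 and Elovl1 rose by 1.31 and 0.75, while Elovl6, Hacd4, Elovl4 and the desaturases Fads2 and Fads1 fell. Adjusted over the list alone 15 passed. Camera did not call the set (median 0.19, adjusted p = 0.428), whereas fry did (adjusted p = 0.0124). Without control replicate 2 the rises numbered 4, and Fads1 missed the threshold without control replicate 1 (adjusted p = 0.0642). In cholesterol biosynthesis 7 of 20 genes rose, 1 fell and 12 did not pass, and 8 passed adjusted over the list alone. The mevalonate pathway enzymes Pmvk and Mvd rose by 1.86 and 0.73 and the sterol cyclase Lss by 0.50, whereas the sterol desaturase Sc5d fell by 0.26. That fall was lost without control replicate 1 or 3 or tumour replicate 1 or 3 (adjusted p up to 0.117) and when arrays were centred on their medians. The set was not called by camera (median 0.20, adjusted p = 0.191) but was by fry (adjusted p = 0.0241). Without control replicate 1 only 4 genes rose.

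Fatty acid uptake, activation and storage rose, with 12 of 25 genes up, 4 down and 9 not past the test (19 past adjusted over the list alone, median 0.25, camera adjusted p = 0.0258). The call was lost at adjusted p = 0.118 with an estimated correlation and at 0.0535 with median-centred arrays. Agpat2, which acylates lysophosphatidic acid, rose by 1.10, the lipid droplet coat protein Plin2 by 0.88 and the fatty acid binding protein Fabp5 by 0.83. The fatty acid transporters Slc27a3, Slc27a2 and Slc27a6 fell, by up to -0.75 for Slc27a3, as did the triglyceride synthase Dgat2. Slc27a6 missed the threshold without control replicate 2 (adjusted p = 0.0635) and Dgat2 without control replicate 1 or 2 (adjusted p up to 0.0957), so that 2 genes fell without control replicate 2. Fatty acid oxidation also rose, with 11 of 24 genes up, 2 down and 11 not past (13 adjusted over the list alone, median 0.19, camera adjusted p = 0.0205), but not at adjusted p = 0.118 with an estimated correlation. The enoyl-CoA isomerase Eci2 and the dehydrogenase Acads rose by 0.77 and 0.63. The medium-chain dehydrogenase Acadm fell by 0.33 and the peroxisomal oxidase Acox2 fell by 0.67, the latter not without control replicate 2 or 3 (adjusted p up to 0.0672).

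Of 20 genes of phospholipid and surfactant lipid synthesis, 11 rose, 4 fell and 5 did not pass, and 15 passed adjusted over the list alone. Pgs1, which makes the precursor of phosphatidylglycerol and cardiolipin, rose by 1.13 (SE 0.06), and Lpcat1, the acyltransferase of surfactant phosphatidylcholine, rose by 0.99 (SE 0.07). The related acyltransferase Lpcat2 fell by 0.71, and Chpt1, Cds2 and Pcyt1b fell as well, Pcyt1b not without control replicate 2 (adjusted p = 0.0539). The set missed the threshold (median 0.23, camera adjusted p = 0.0719), which it passed at 0.0452 without genes of low signal and at 0.0479 with camera on ranks.

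Genes that supply NADPH rose. In the list of the pentose phosphate pathway and NADPH supply 10 of 13 genes rose, 0 fell and 3 did not pass, with the same number of 10 past when adjusted over the list alone (median 0.55, camera adjusted p = 0.000276). This gave adjusted p = 0.111 with an estimated correlation. The mitochondrial folate enzyme Mthfd2 rose by 1.90 (SE 0.21), Me1 by 1.13, and Pgd, a dehydrogenase of the oxidative branch, by 0.89 (SE 0.07). In glycolysis 12 of 20 genes rose, 2 fell and 6 did not pass, and 15 passed adjusted over the list alone. Hexokinase 2 (Hk2) rose by 1.79 (SE 0.13), the aldolase Aldoc by 1.34 and the fructose 2,6-bisphosphate regulator Pfkfb4 by 0.93, while Pfkfb3 of the same enzyme family fell by 0.76 and the muscle phosphofructokinase Pfkm fell by 0.35. The glycolysis set shifted up (median 0.39, camera adjusted p = 0.0338), but not with an estimated correlation (adjusted p = 0.472), without control replicate 3 (adjusted p = 0.0512) or with median-centred arrays (adjusted p = 0.0685). Without control replicate 2 the rises numbered 8, and 4 genes were lower without tumour replicate 2. In oxidative phosphorylation 20 of 29 genes rose, 0 fell and 9 did not pass, and 23 passed adjusted over the list alone (median 0.30, camera adjusted p = 1.86e-05). The set had adjusted p = 0.363 with an estimated correlation. The cytochrome oxidase subunits Cox4i1 and Cox5a rose by 0.73 and 0.67 and the ATP synthase subunit Atp5o by 0.66.

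Targets of NRF2, the transcription factor of the oxidative stress response, divided. Of 18 measured, 10 rose, 4 fell and 4 did not pass, and 14 passed adjusted over the list alone. The cystine transporter Slc7a11 rose by 2.27 (SE 0.16), the heme oxygenase Hmox1 by 1.58 (SE 0.07) and Osgin1 by 1.48, whereas the glutathione transferases Gstm1 and Gstm3 fell by 1.09 and fell by 1.02, the epoxide hydrolase Ephx1 fell by 0.93 and the exporter Abcc1 fell by 0.35. The set shifted up (median 0.70, camera adjusted p = 0.0231), with adjusted p = 0.523 with an estimated correlation, 0.0739 without tumour replicate 5, 0.0689 with median-centred arrays and 0.148 with the replicate number as a block. Xenobiotic metabolism, which in lung is carried largely by club cells, fell. Of its 20 genes 18 fell, 0 rose and 2 did not pass (Gstt1 at 0.017 and Sult1a1 at 0.077), and 18 passed adjusted over the list alone. Sult1d1 fell by 3.25, the monooxygenase Fmo1 fell by 2.57 (SE 0.15) and the retinal dehydrogenase Aldh1a1 fell by 2.34 (SE 0.15). As a set these genes shifted down (median -1.38, camera adjusted p = 5.64e-11), a call lost at adjusted p = 0.0968 with an estimated correlation.

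Transcriptional targets and feedback regulators of ERK signalling, which lies downstream of Ras, rose. In that list 16 of 22 genes rose, 1 fell and 5 did not pass, and 18 passed adjusted over the list alone. The growth factor Ereg rose by 2.38 (SE 0.19), the phosphatase Dusp4 by 1.77 (SE 0.20) and Myc by 1.61 (SE 0.20). The related phosphatase Dusp6 rose by 0.36 (SE 0.10, limma adjusted p = 0.0169). Ier3 fell by 0.37. Dusp6 missed the threshold without control replicate 1 or 2 (adjusted p up to 0.0582) and Ier3 without control replicate 1 (adjusted p = 0.052) and with the replicate number as a block. The set shifted up (median 0.63, camera adjusted p = 8.16e-05), with adjusted p = 0.274 with an estimated correlation.

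Cell cycle genes rose in part, with 15 of 31 up, 0 down and 16 not past the test, and 17 passed adjusted over the list alone. The spindle checkpoint kinase Bub1b rose by 0.94 (SE 0.16), the mitotic kinases Plk1 and Cdk1 by 0.71 and 0.68, and the proliferation marker Mki67 by 0.67 (SE 0.21, limma adjusted p = 0.0285). The set shifted up (median 0.42, camera adjusted p = 0.00264), with adjusted p = 0.591 with an estimated correlation and 0.0784 with fry. The mean of the list stood at 0.92 above the controls in tumour replicate 2 and at 0.23 to 0.33 in the other tumour arrays. Without that array 19 genes rose and 2 fell, and without control replicate 1 or 2 only 8 rose. Mki67 missed the threshold without any 1 of the 3 control arrays or tumour replicate 1 (adjusted p up to 0.0937) and with a variance trend, and Cdk1 without control replicate 1 (adjusted p = 0.067).

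Among 12 genes of senescence and cell cycle inhibition 7 rose, 2 fell and 3 did not pass, with 9 past adjusted over the list alone. Camera did not call the set (median 0.25, adjusted p = 0.279), whereas fry did (adjusted p = 0.000851). The transcriptional repressor Bhlhe40 rose by 1.75 and the urokinase receptor Plaur by 0.79, and the cyclin-dependent kinase inhibitor Cdkn2c and the secreted protein Igfbp7 fell by 0.87 and fell by 0.25. Without control replicate 1 or 2 the rises numbered 3. Of 18 gastrointestinal differentiation markers 8 rose, 1 fell and 9 did not pass, and 9 passed adjusted over the list alone. The tight junction protein Cldn2 rose by 1.63 and the gastrokine Gkn2 by 1.20, both from low signals, while Gkn3 fell by 0.75. The set missed the threshold (median 0.26, camera adjusted p = 0.103). It passed at adjusted p = 0.0468 with the replicate number as a block and at 0.0221 with fry. Without control replicate 1 its rises numbered 5. Without tumour replicate 2 the mean change of this list was 0.16 in place of 0.30, and 2 genes fell.

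Epithelial markers moved in opposite directions. Of 19 alveolar type 2 cell markers, 6 of which also stand in other lists, 16 rose, 1 fell and 2 did not pass, with 17 past adjusted over the list alone. The surfactant-processing protease Napsa rose by 1.51 (SE 0.08), the alarmin Il33 by 1.01 and Lpcat1 by 0.99. Sftpc, the surfactant protein that defines these cells, was already near the top of the measured range, which ends at 13.14 and where differences can be understated (12.63 ± 0.05, SD, n = 3), and changed by 0.11 (SE 0.06, limma adjusted p = 0.193), which passed only with median-centred arrays, at 0.19. The lysozyme Lyz1 fell by 0.21, a call lost without control replicate 1 (adjusted p = 0.0611), with median-centred arrays and with the replicate number as a block. The set shifted up (median 0.53, camera adjusted p = 4.06e-06), with adjusted p = 0.0968 with an estimated correlation. Of 17 alveolar type 1 cell markers 2 rose, 8 fell and 7 did not pass, and 10 passed adjusted over the list alone. Igfbp2 and Rtkn2 fell by 1.37 and fell by 1.26, whereas the water channel Aqp5 rose by 0.82 and the keratin Krt7 by 0.25. Krt7 kept its call only without tumour replicate 2 (adjusted p up to 0.193 without each of the others), and 4 type 1 markers rose without that array but only 1 without any other. Taken as a whole the list shifted down (median -0.28, camera adjusted p = 0.00646), with adjusted p = 0.49 with an estimated correlation.

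Airway cell markers fell. Of 18 club cell markers 11 fell, 1 rose and 6 did not pass, and 15 passed adjusted over the list alone. Chad, a leucine-rich matrix protein, fell by 2.83 (SE 0.50), Lypd2 fell by 2.11 (SE 0.37) and the GABA receptor subunit Gabrp fell by 1.53 (SE 0.20), while the stress-induced regulator Nupr1 rose by 0.95. Scgb1a1, the club cell secretory protein whose promoter drives Cre in these mice, fell from 12.59 ± 0.08 (SD, n = 3) to 12.22 ± 0.15 (SD, n = 5), a log2 change of -0.37 (SE 0.09, limma adjusted p = 0.00933). Its signal, like that of Sftpc, lies near the top of the range, so this fall can be understated. A downward shift of the whole list was called (mean -0.98, camera adjusted p = 4.28e-05), with adjusted p = 0.118 with an estimated correlation. Its mean stood at -0.549 and -0.538 in tumour replicates 2 and 5 and at -1.097 to -1.373 in the other tumour arrays. Of 22 ciliated cell markers 21 fell, 0 rose and 1, Mcidas, did not pass (0.15), and 21 passed adjusted over the list alone. The axonemal protein Rsph4a fell by 2.08 (SE 0.27), Sntn fell by 1.90 (SE 0.30) and Cdhr3 fell by 1.70 (SE 0.21). The set shifted down (median -1.31, camera adjusted p = 6.38e-11), with adjusted p = 0.274 with an estimated correlation.

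Vascular and stromal markers fell broadly. Of 26 endothelial cell markers 25 fell, 1 rose and 0 did not pass, and 26 passed adjusted over the list alone. Tmem100 fell by 2.57 (SE 0.12), the endothelin receptor Ednrb fell by 2.34 (SE 0.15) and the VEGF receptor Kdr fell by 2.06 (SE 0.10), while the carbonic anhydrase Car4 rose by 0.31. The rise of Car4 missed the threshold without any 1 of the 3 control arrays or tumour replicate 4 or 5 (adjusted p up to 0.179), after a second quantile normalization, with the replicate number as a block and with tumour replicates 3 and 4 averaged. As a set these genes shifted down (median -1.39, camera adjusted p = 3.19e-20), with adjusted p = 0.0625 with an estimated correlation. Of 20 fibroblast markers 17 fell, 1 rose and 2 did not pass (18 adjusted over the list alone). Ogn fell by 3.36, the integrin Itga8 fell by 3.03 (SE 0.15) and the matrix protein Dpt fell by 2.17 (SE 0.12), while Serpinf1, a secreted inhibitor of angiogenesis, rose by 1.00. The median was -1.20 (camera adjusted p = 5.18e-11), with adjusted p = 0.0968 with an estimated correlation. Of 16 smooth muscle and pericyte markers 12 fell, 1 rose and 3 did not pass (13 adjusted over the list alone). The contractile proteins Cnn1 and Des fell by 2.58 and fell by 1.88, and the pericyte regulator of G protein signalling Rgs5 rose by 2.12 (SE 0.24). That list had a median of -0.88 (camera adjusted p = 4.78e-08), with adjusted p = 0.0968 with an estimated correlation.

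Heart muscle transcripts, which in mouse lung come from the muscle around the pulmonary veins and from any attached heart tissue, were abundant in the controls and fell. Of 14 such markers 13 fell, 0 rose and 1 did not pass (Mybpc3, 0.028), and 13 passed adjusted over the list alone. Actc1 fell by 3.26, the calcium pump regulator Pln fell by 2.86 (SE 0.25) and the atrial myosin light chain Myl4 fell by 2.85 (SE 0.29). Taken as a whole the list shifted down (median -1.62, camera adjusted p = 2.35e-09), with adjusted p = 0.118 with an estimated correlation. Of 11 adipocyte markers 7 fell, 0 rose and 4 did not pass, and 8 passed adjusted over the list alone. Retn, the hormone resistin, fell by 1.92, the hormone adiponectin (Adipoq) fell by 1.44 and the lectin Lgals12 fell by 1.08. A downward shift of the whole list was called (median -0.45, camera adjusted p = 0.00954), with adjusted p = 0.272 with an estimated correlation. Extracellular matrix genes and their proteases went both ways, with 6 of 25 up, 7 down and 12 not past, and 14 past adjusted over the list alone. Ctsk and the macrophage elastase Mmp12 rose by 2.88 and 1.73, and the stromelysin Mmp3 fell by 1.84. Mmp12 was 9.48 in tumour replicate 2 and at most 7.21 in the other tumour arrays, and it missed the threshold without control replicate 1 or 3 (adjusted p up to 0.0667) and with a variance trend. The median (-0.054) and the mean (0.015) of this list differ in sign, and camera placed it lower without a call (adjusted p = 0.271). Neither sign is stable, since the median was 0.046 without control replicate 2 and the mean -0.034 without control replicate 1.

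Immune markers also divided. Of 22 macrophage markers 14 rose, 3 fell and 5 did not pass, and 19 passed adjusted over the list alone. Gpnmb rose by 2.96, the proton pump subunit Atp6v0d2 by 2.43 (SE 0.12) and the chitinase-like lectin Chil3 by 2.28 (SE 0.22), while the keratin Krt79 fell by 1.17, the lipid droplet protein Cidec fell by 0.95 and the growth factor receptor Csf1r fell by 0.51. Csf1r missed the threshold without any 1 of the 3 control arrays or tumour replicate 3 or 4 (adjusted p up to 0.0878). The set shifted up (median 0.92, camera adjusted p = 3.17e-05), with adjusted p = 0.338 with an estimated correlation.

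Lymphocyte markers fell. Of 20 T and NK cell markers 19 fell, 0 rose and 1 did not pass (Foxp3, -0.21), and 19 passed adjusted over the list alone. Nkg7 fell by 3.18, the natural killer receptor Ncr1 fell by 3.07 (SE 0.16) and the granzyme Gzma fell by 2.78 (SE 0.15). The set shifted down (median -1.30, camera adjusted p = 1.46e-14), with adjusted p = 0.0968 with an estimated correlation. Of 14 B and plasma cell markers 12 fell, 0 rose and 2 did not pass (Jchain, -1.15, and Derl3, 0.31), and 12 passed adjusted over the list alone. Ms4a1 fell by 3.51, the B cell receptor chain Cd79a fell by 2.91 (SE 0.12) and the transcription factor Spib fell by 2.47 (SE 0.13). As a set these genes shifted down (median -1.53, camera adjusted p = 5.71e-10), with adjusted p = 0.0968 with an estimated correlation.

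Of 16 neutrophil markers 5 fell, 0 rose and 11 did not pass, and 3 passed adjusted over the list alone. The calprotectin subunit S100a9 fell by 1.42 (SE 0.29), the gelatinase Mmp9 fell by 1.29 (SE 0.22) and the growth factor receptor Csf3r fell by 1.13 (SE 0.23), and S100a8 and the granule protein Ngp fell by 1.05 and fell by 0.64. The control arrays differed among themselves, since the mean of the list stood at 0.58 in control replicate 1 and at -0.28 and -0.30 in the other control arrays. Tumour replicate 2 showed no fall, at -0.004, and the other tumour arrays stood at -0.704 to -0.747. Without control replicate 1 the change was -0.45 for S100a8 (adjusted p = 0.0887) and -0.38 for Ngp (adjusted p = 0.207), the mean change of the list was -0.29 in place of -0.58, and 3 genes fell. S100a8 was also lost without tumour replicate 1, 3 or 5 (adjusted p up to 0.0817), and Ngp without control replicate 2 or tumour replicate 1, 3, 4 or 5 (adjusted p up to 0.0822). Without tumour replicate 1, 3 or 5, too, 3 genes fell. Taken as a whole the list shifted down (median -0.58, camera adjusted p = 0.00714), with adjusted p = 0.472 with an estimated correlation, 0.0559 without genes of low signal and 0.0903 with fry.

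Of 32 chemokines and inflammatory cytokines 13 rose, 6 fell and 13 did not pass, with 20 past adjusted over the list alone. Camera did not call the set (median 0.34, adjusted p = 0.376). The myeloid growth factor Csf2 rose by 2.53 (SE 0.29) and the chemokine Ccl6 by 1.74 (SE 0.11), whereas Ccl5, a chemokine made by cytotoxic lymphocytes, fell by 2.34 (SE 0.16). Of 20 interferon response genes 7 fell, 0 rose and 13 did not pass, and 7 passed adjusted over the list alone. Ifit1, Oasl2 and Ifit2, which act against viral RNA or are induced with such genes, fell by 0.80, fell by 0.78 and fell by 0.76. Ifit1 missed the threshold without any 1 of the 3 control arrays or tumour replicate 1 (adjusted p up to 0.096) and with array weights or a variance trend, and Oasl2 without any 1 of the 3 control arrays or tumour replicate 2 (adjusted p up to 0.105) and with a variance trend. The number of interferon genes that fell was 2 without control replicate 2, 3 without control replicate 1 or 3, 4 without tumour replicate 1 and 11 without tumour replicate 4. A downward shift of the whole list was called (median -0.38, camera adjusted p = 0.00132), with adjusted p = 0.472 with an estimated correlation and 0.0784 with fry. The fall was uneven. The mean of the list stood at -0.094 and -0.102 in tumour replicates 3 and 4, close to the controls (-0.043 to 0.063). In the other tumour arrays it stood at -0.383 to -0.816.

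In antigen presentation by MHC class II, 6 of 10 genes rose, 2 fell and 2 did not pass, with 9 past adjusted over the list alone. Camera did not call the set (median 0.37, adjusted p = 0.214). The lysosomal protease Ctss rose by 1.20 (SE 0.12). The members that fell were H2-Ob and H2-Oa, chains of the peptide-loading modulator found mainly in B cells, which fell by 2.70 (SE 0.11) and fell by 1.04 (SE 0.11).

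Clock genes changed in opposite directions, and camera did not call the list, whereas fry did (adjusted p = 0.0355). Of 16 measured, 6 rose, 2 fell and 8 did not pass, and 11 passed adjusted over the list alone (median 0.41, camera adjusted p = 0.204). Dbp, an output of the clock, rose by 1.49 (SE 0.31), its repressors Bhlhe41 and Per2 rose by 1.48 (SE 0.14) and 1.33 (SE 0.19), and the activators Arntl and Clock fell by 1.26 (SE 0.26) and fell by 0.48 (SE 0.09). Of 16 immediate early genes, which respond within minutes to stimuli and to tissue handling, 3 rose, 6 fell and 7 did not pass, and 9 passed adjusted over the list alone (median -0.06, camera adjusted p = 0.0998). Egr2, Atf3 and Junb rose by 0.95, 0.91 and 0.55, and Klf2, a factor of quiescent endothelium and lymphocytes, fell by 1.27 (SE 0.08). Of 4 measured red blood cell genes, too few for a set test, 1 rose (Epb42, 0.79), 0 fell and 3 did not pass, and 1 passed adjusted over the list alone.

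**Figure D3:**
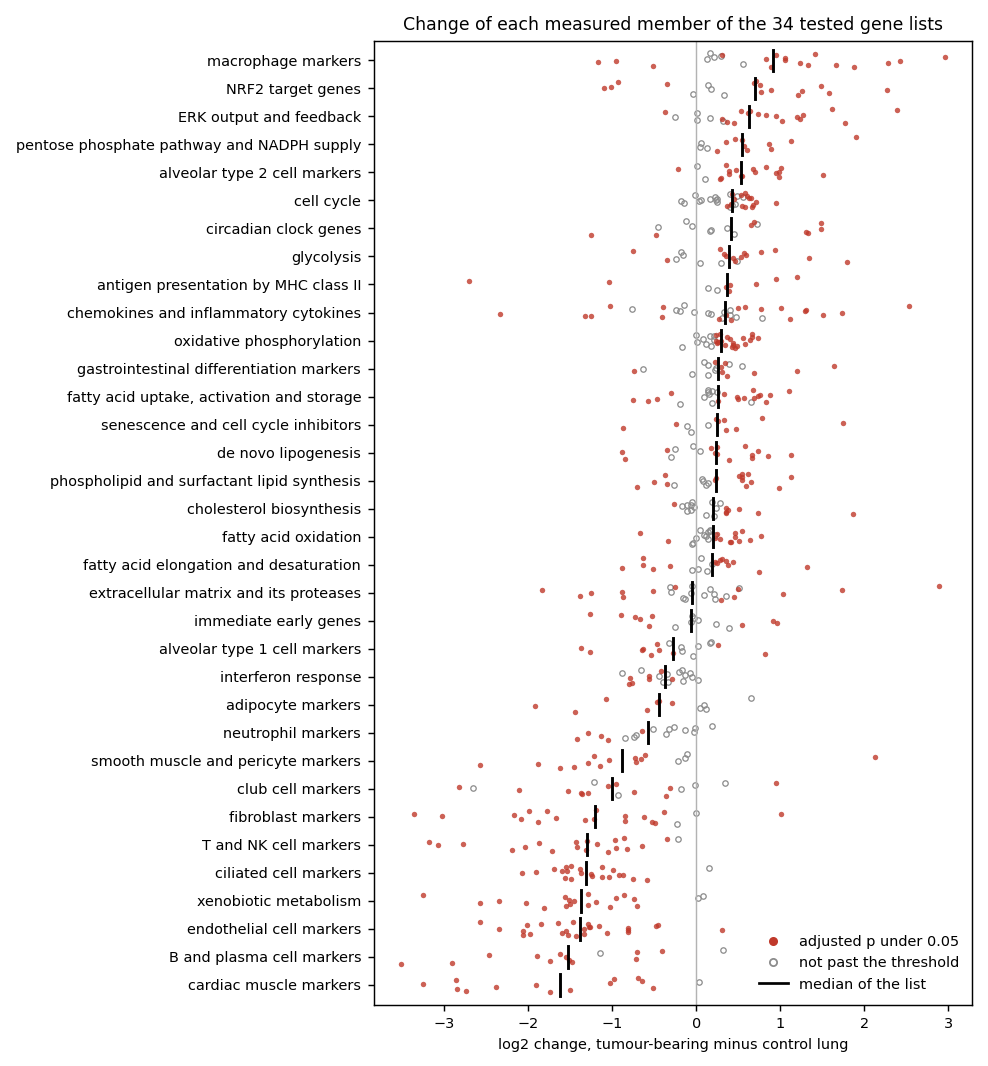
Log2 change, tumour minus control (horizontal axis), of each measured gene in the 34 tested lists (vertical axis). Filled points passed an adjusted p of 0.05 and open points did not, and the black bars are list medians, which run from 0.92 for macrophage markers to -1.62 for cardiac muscle markers.

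In all, camera called 23 of the 34 tested lists, 10 up and 13 down, and 0 of the 34 with an estimated correlation, where the lowest adjusted p was 0.0625 and 12 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list changed at all and not whether it shifted against the other genes, called 28. It did not call the cell cycle, interferon and neutrophil lists, which camera called, nor chemokines, MHC class II and extracellular matrix. Fry, but not camera, called lipogenesis, elongation and desaturation, cholesterol, phospholipids, senescence, gastrointestinal markers, clock genes and immediate early genes. The counts of changed genes within the lists do not depend on that correlation.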

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

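The splits of the arrays were planned before the result was seen, and the tests of cell-type, clock and lipogenesis explanations below were chosen after it was seen. Among 169 named genes and lists, the array farthest from the others of its group was compared with its nearest neighbour, and 25 (20 of 133 genes and 5 of 36 lists) had a tumour array standing apart. Such a test marks about 1 in 20 groups by chance. Tumour replicate 2 accounted for 20, replicate 5 for 3 and replicate 1 for 2.

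In tumour replicate 2 the signal was higher than in the other tumour arrays for Mmp12 (9.48 against at most 7.21), Chad (9.1 against at most 7.17), Il33 (10.91 against at most 9.76), Fabp5 (10.47 against at most 9.7), Bub1b (7.67 against at most 7.05), Plk1 (7.25 against at most 6.71), Krt79 (6.33 against at most 5.73), Retn (6.12 against at most 5.49), Ctss (10.56 against at most 10.09), Atp6v0d2 (11.28 against at most 10.88), Acly (10.12 against at most 9.75), Car4 (11.78 against at most 11.43) and Cox5a (9.2 against at most 8.94). It was lower for Sprr1a (9.23 against at least 10.14), Prmt8 (8.64 against at least 9.17) and Lpcat1 (11.8 against at least 11.99). Relative to the controls, its mean shift was 0.917 for cell cycle genes (others at most 0.329), 1.189 for macrophage markers (at most 0.83), -0.004 for neutrophil markers (at most -0.704) and -0.525 for type 1 cell markers (at least -0.26).

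In tumour replicate 5 Gabrp was 10.1 (others at most 9.25), Ms4a1 was 4.2 (at least 4.58) and the xenobiotic list stood at -1.046 (at most -1.424). In tumour replicate 1 Pgd was 10.23 (others at least 10.35) and Cd79a was 5.98 (at least 6.29).

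Among the 56 splits of the 8 arrays into 3 and 5, the real split called 8097 genes and the highest other 9, so 1 split in 56 gave as many. For genes changed at least 2-fold the real split gave 1377 and the highest other 6, again 1 split. For gene lists the real split called 23 and another 25, and 7 splits gave as many. The split that called 25 set control replicates 2 and 3 and tumour replicate 1 against the rest, so it kept part of the real contrast. A split of tumour replicates 1, 2 and 5 against the other 5 arrays called 24. Mixed splits also widen the spread within a group, which lowers their gene counts. Their counts therefore do not show what unrelated groups would give. For the lipogenesis list the camera p was 0.111, the lowest of another split 0.0661, and 7 splits gave one as low. These numbers of splits include the real one. The rule set beforehand asked for a share of splits under 0.05. The list count and the lipogenesis p did not meet it, so neither stood apart from the other splits. Both gene counts met it, with the limit given above for mixed splits.

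Markers of many normal lung cell types fell together. If all normal cells were diluted alike and no other cell carried their markers, their shifts would be equal. The type 1 shift minus the T and NK shift was 0.936 to 1.384 in the single tumour arrays (mean 1.18). The type 1 list holds markers that rose, such as Aqp5 (0.82), so it does not follow type 1 cells alone. The gap therefore cannot decide on one common dilution. This pair of lists was chosen after their shifts were seen, so no p-value is given. Mesothelial markers outside the largest changes had a median change of -0.74. A smaller share of pleura in the tumour samples may contribute, but a dilution of normal cells would lower these markers as well. Loss of cells and lower expression per cell were not separated.

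Clock genes moved in opposite directions. The Per and Dbp shift minus the Arntl and Clock shift was 1.6 higher in the tumour arrays. This difference ranged over 0.689 within the control arrays and varied widely within the tumour arrays, from 0.901 to 2.385. The difference is taken over genes that include those that showed the pattern, so it measures the size of the pattern and tests no explanation. The hours of collection are not in the labels, so a different hour and a change of the clock within the tissue cannot be told apart.

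Lipogenic enzymes rose beside type 2 cell markers. The largest rise in the lipogenesis list was 1.13 (Me1), and the largest of a type 2 marker was 1.51 (Napsa), but comparing these largest values does not test a change in the share of cells. The median of the type 2 markers was 0.53 while Fasn rose by 0.85, Srebf1 by 0.73 and Acaca by 0.66, and Elovl6 and Acss2 fell by 0.89 and fell by 0.85. A larger share of type 2-like cells and a rise within each cell cannot be told apart, since whole tissue was measured.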

How the results depend on the processing

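Of the 133 genes named by the rule, 118 kept their direction and their side of the threshold of 0.05 in every refit that followed them (127 of the 133 were in the one without genes of low signal), as did 27 of the 33 lists besides lipogenesis in every refit with the preset correlation, and no result reversed. The stricter threshold and the fit of every probe set followed counts only. The 25 called genes named because a count was 5 or fewer were followed only in the fits that leave out 1 array. The further genes named for missing the threshold were not followed singly in any refit. Centring the arrays on their medians gave 7026 genes higher, and an adjusted p under 0.01 gave 2889 higher, as a stricter threshold must. The cause of the former is the median change of all genes, which the centring shifts from 0.0747 to 0.153. With an estimated correlation 0 lists were called. The lipogenesis list passed no camera test. It passed with fry, at 0.000255, which asks another question, since fry tests a list against no change and camera against the other genes. Leaving out each array in turn gave 3488 to 4750 genes higher, 3018 to 3629 lower, 1366 to 1425 changed at least 2-fold, 22 to 23 lists and a lipogenesis p of 0.114 to 0.185. Such fits have 5 residual degrees of freedom in place of 6, so a call can be lost at a similar change. Mki67 changed by 0.662 without control replicate 2 and by 0.665 with all arrays. S100a8 and Ngp, in contrast, also shrank without control replicate 1, to -0.45 and -0.38. Of the 8097 calls, 6354 to 7763 were kept and 0 turned.

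With the replicate number as a block 3529 genes were higher, 2976 lower and 23 lists called. NRF2 targets were lost (0.148) and gastrointestinal markers gained (0.0468), and Scd1, Scd2, Ier3, Lyz1 and Car4 missed the threshold. Tumour replicates 4 and 5 share no number with a control, so each formed a block alone and added nothing to the group difference. That fit had 2 residual degrees of freedom, and its lost and gained calls do not show an effect of pairing. The residuals of same-numbered arrays correlated at -0.215, 0.009 and 0.054, and those of differently numbered arrays at -0.15 to 0.235. These values show no pairing by number, but so few arrays cannot exclude one. Averaging tumour replicates 3 and 4, the closest pair, which was chosen after seeing the data, gave 4161 higher and 3320 lower. Alternatives on the level of Kras were not run, since Kras is not analysed here. Low signals can limit precision. Without genes of a mean under 5.42, 4196 of the 13292 genes left were higher and 3203 lower, counts that do not measure that limit.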

Other observations

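The tests in this part were chosen after the result was seen. A rise of genes of amino acid supply and of the response led by the transcription factor ATF4 was a hypothesis that came from the amino acid transporters and 1-carbon enzymes Slc7a5 (2.57), Slc7a11 (2.27), Mthfd2 (1.90) and Aldh1l2 (1.88, from a low control mean of 4.69) among the largest rises. Of 22 other genes of this list, which lie outside the 80 largest rises and 60 largest falls but include Atf4 itself and Atf3 and Nupr1, already named in the report, 18 rose, 0 fell and 4 did not pass (median 0.573, camera adjusted p = 8.6e-06), with adjusted p = 0.264 with an estimated correlation. Sesn2 rose by 1.56, Trib3 by 1.48, the serine synthesis enzymes Psat1 and Phgdh by 1.44 and 1.15, and the asparagine synthetase Asns by 1.27.

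A rise of lysosomal genes was a hypothesis that came from Gpnmb, Ctsk, Atp6v0a4 and Atp6v0d2 among the largest rises. Of 23 other genes of lysosomes, the proton pump and their transcription factors Mitf and Tfeb 19 rose, 0 fell and 4 did not pass (median 0.582, camera adjusted p = 1.43e-07), with adjusted p = 0.264 with an estimated correlation. Npc2 rose by 1.11, Mitf by 1.10, Gla by 1.08 and Ctsd, which also stands in the macrophage list, by 0.95. Macrophage markers rose in the same samples, and the cell types that carry these transcripts are unknown.

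A squamous programme was the hypothesis drawn from Sprr1a (2.81), S100a14 (2.56), Tgm1 (2.47), Spink5 (2.16), Ivl (2.06), Klk14 (1.98) and Trim29 (1.82). The control means of S100a14 (5.04) and Ivl (4.57) are low, so the sizes of these changes are inexact. Of 17 other cornified and squamous genes 3 rose, 0 fell and 14 did not pass (median 0.119, camera adjusted p = 0.157), and the basal cell genes Krt5 (-0.021), Trp63 (0.021) and Krt14 (0.17) did not pass. Of the genes that did not pass, Krt5, Sprr3, Tgm3, Lor, Krt1, Krt10, Krt6a, Dsg3, Dsc3 and Krtdap lay under 5.42 in both groups. A change can be missed at such signals, although Sprr1b and Cdsn rose from them.

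Of 12 mesothelial markers 8 fell, 3 rose and 1 did not pass (median -0.74, camera adjusted p = 0.0036), with adjusted p = 0.264 with an estimated correlation. Upk1b and Rspo1 fell by 2.25 and fell by 1.57, while the keratins Krt18 and Krt8, which other epithelia share, rose by 1.13 and 0.79.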
